A study of Mus musculus with 4 samples.

How the data were processed

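Single-cell RNA sequencing was done on CD45-positive, CD11b-positive cells sorted from the ovaries of virgin C57BL/6J mice at 2 ages, labelled 3 months and 15 months. For each age there were 3 hashtag pools, that is, cell suspensions marked with an antibody carrying a barcode that the sequencing reads out, and these 3 pools were joined before 1 sort and 1 Chromium 3' library. Age and library therefore cannot be told apart, and every p-value here measures the spread between pools inside libraries, not between libraries. The labels differ on the animals. The series description gives 2 mice for every pool, while the protocol gives harvest ages of 2 to 3 and 14 to 17 months, 6 young animals with 2 to a pool, and 5 old animals with 1 pool from a single mouse, and does not say which. The pools were treated as the units of replication, 3 of each age.

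The deposited matrices hold raw UMI counts for 31053 genes and 3 hashtags over the barcodes that Cell Ranger had called as cells, with no normalization by the authors. The matrix headers name Cell Ranger 4.0.0, whereas the processing notes list Cell Ranger 7.0.0, FastQC 0.11.4 and mm10, so the version used is open. The target was 8000 cells for each library. Of the gene IDs, 30934 were found in GENCODE M21 (GRCm38), which gave the positions, and 35 symbols belonged to more than 1 gene ID.

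The 3-month library held 3135 barcodes with 27277073 gene UMIs (median 7472 to a barcode) and 6493788 hashtag counts. The 15-month library held 4939 barcodes with 45060166 gene UMIs (median 6949) and 12769587 hashtag counts. Hashtags were called in each library alone with HTODemux of Seurat 5.3.0 (centred log ratio over cells, positive quantile 0.99), which gave 361 doublets, 640 negatives and 2134 singlets at 3 months. At 15 months it gave 321 doublets, 413 negatives (1 of them with no hashtag count) and 4205 singlets. Singlets with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept, 1837 at 3 months and 3833 at 15 months, 5670 in all. Doublets inside a pool carry 1 hashtag and stay in: from the hashtag doublets about 199.6 were estimated among the kept 3-month cells (10.9%) and 218.9 among the kept 15-month cells (5.71%).

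Both libraries were clustered together in scanpy 1.11.5 with leidenalg 0.10.2, igraph 0.11.9 and Python 3.11.15: counts scaled to 10000, log1p, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.6, seed 1 and no integration. Each of the 19 clusters was scored on fixed marker sets and named only where the best set had at least 3 markers seen in at least 20% of its cells, a score of at least 0.5 and a lead of at least 0.25 over the next set, and where no other set had more markers among the 10 genes most raised in the cluster. These naming limits were set after the clusters had been seen. Clusters 1, 15 and 16 scored highest for macrophage markers but did not meet the naming rule, and they are reported by number.

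Raw UMI counts were summed for each pool and class, and classes with at least 10 cells in each of the 6 pools were tested (7 classes, and all kept cells together). Age was tested as 15 months over 3 months with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), after filterByExpr and TMM, with Benjamini-Hochberg adjustment inside each class and a threshold of 0.05. Levels are CPM, the UMI counts scaled by TMM library size, or for numbered clusters by all UMIs of the cluster. The difference between age effects in 2 classes was tested as an interaction term with the pool as a block. Cells per class were tested with the same edgeR method on cell numbers, offset by the cells of the pool, with a two-sided exact permutation test beside it, whose smallest possible p for 3 against 3 pools is 0.1. Gene lists (19 for functions and states, 13 for markers of other cell types) were tested where at least 3 members were measured, with camera in limma 3.58.1 on log2 CPM (prior count 2, inter-gene correlation 0.01), with camera using an estimated correlation, and with fry. Intervals for shares of cells in 1 pool are Wilson intervals at 95%, the floor for a count of 0 is 3 counts, and both cover counting error only.

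The lists, the comparisons, the tests, the alternatives and the rule for naming genes were fixed before the data were examined, apart from what is named here as added. The rule took, in macrophage-like cells and in all cells, up to 8 genes with the largest rise and 8 with the largest fall among those past the threshold with a mean of at least 50 CPM and no overlap between ages, and the 3 members of every list with the smallest p. Other classes had 4 in place of 8, and members only of lists past the set test. Predicted gene models were counted but not named by the rule. Genes past the threshold that the rule leaves out were named after their values were seen: Hbb-bt, Fcna, Aig1, Gm42418 and, in the other classes, those said to be below the rule. Some genes that the rule names are not reported here.

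The alternatives were DESeq2 1.42.0 in place of edgeR, median-ratio factors (RLE), no low-count filter, a mean of at least 50 CPM, pool number as a block, leaving out each pool, a hashtag ratio rule (top hashtag with at least 10 counts and 3 times the next), MULTIseqDemux, a loose cell filter (200 genes, 500 UMIs, 20% mitochondrial), a strict one (1000 genes, 2000 UMIs, 5%), removal of scrublet calls, thinning of the deeper library to 88.8% of its UMIs, and Leiden resolutions 0.3 and 1.0. A wider macrophage class, clusters 2 and 6 alone, and cells under 1% haemoglobin UMIs were added after seeing the data. Scrublet marked 3 of 2232 barcodes at 3 months and 3 of 4347 at 15 months, while hashtags had marked 332 and 300 of them as doublets, so that its removal says nothing on doublets. Counts were simulated with the same spread and known changes, set only in up to 200 genes of at least 50 CPM. In macrophage-like cells (8356 genes tested) the test found 19.4% of the 1.5-fold, 88.06% of the 2-fold and 100% of the 4-fold changes. The same test found 1.49%, 25.8% and 95.3% in classical monocyte-like cells (3911 genes tested). The interaction test found 1.49%, 2.99% and 36.4% (6852 genes tested). Barcodes called negative or doublet were left out of all tests. Other tools were anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.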

Results

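The data were single-cell transcriptomes of CD11b-positive immune cells from mouse ovary at 3 and 15 months of age, with 3 hashtag pools of each age. The series title names the question as what aging changes in the macrophages of the ovary. The 3-month pools held 468, 449 and 920 kept cells with 2972982, 4094153 and 8043290 UMIs, and the 15-month pools held 739, 2205 and 889 cells with 5407277, 22102248 and 8010620 UMIs. Each age was 1 sort and 1 library, so an age difference and a library difference cannot be told apart in any value below. Chi-square over its degrees of freedom between pools of one age ran from 4.49 to 13.5, so pools of one age differed by more than counting error.

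The first comparison asked how the make-up of the sorted cells differed between ages. B cell-like cells, which carry the B cell receptor genes, were the class whose share rose: they made up 0.765 ± 0.296% of cells at 3 months and 7.19 ± 2.69% at 15 months (SD, n = 3 pools each), a log2 ratio of 3.16 ± 0.68 (SE, edgeR adjusted p = 0.00397). Their number was 2 of 468, 4 of 449 and 9 of 920 cells in the 3-month pools, and 73 of 739, 99 of 2205 and 64 of 889 in the 15-month pools. The Wilson intervals ended at or below 2.27% in every 3-month pool and began at or above 3.70% in every 15-month pool. The exact permutation p was 0.1, the smallest that 3 against 3 pools allow, and without the second 3-month pool the edgeR adjusted p was 0.0516.

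No other class passed the test of shares. Macrophage-like cells made up 29.5 ± 7.29% at 3 months and 21.2 ± 1.09% at 15 months (log2 ratio -0.48 ± 0.54, edgeR adjusted p = 0.490), and every 15-month pool lay below every 3-month pool. NK cell-like cells stood at 10.3 ± 4.45% and 5.14 ± 1.26% (adjusted p = 0.299), again without overlap. Type 1 dendritic cell-like (cDC1-like) cells stood at 5.53 ± 2.96% and 1.54 ± 1.43% (log2 ratio -1.78 ± 0.72, adjusted p = 0.180). This share passed with the pool number as a block (log2 ratio -1.98), with the strict cell filter (-1.70), at Leiden resolution 1.0 (-1.76) and without the second 15-month pool (-2.92). Of the cDC1-like cells counted, 20 of 116 at 3 months and 1 of 82 at 15 months had over 1% haemoglobin UMIs. Type 2 (cDC2-like) cells stood at 11.4 ± 4.45% and 6.68 ± 2.35%. Neutrophil-like cells stood at 6.72 ± 5.86% and 12.1 ± 1.68%, non-classical monocyte-like cells at 7.47 ± 3.39% and 11.4 ± 5.79%, and classical monocyte-like cells at 9.05 ± 7.15% and 7.17 ± 2.85%. T cell-like cells stood at 1.35 ± 1.05% and 2.64 ± 2.15%, mature dendritic cell-like cells at 2.19 ± 0.836% and 1.30 ± 0.829%, cycling cells at 2.04 ± 1.05% and 2.74 ± 0.770%, and mast cell or basophil-like cells at 0.147 ± 0.127% and 0.709 ± 0.625%. Stroma or fibroblast-like cells, which a CD45 gate should not hold, stood at 7.83 ± 2.01% and 6.70 ± 1.85%. The unnamed clusters 1, 15 and 16 together made up 5.69 ± 3.93% and 13.6 ± 6.89% (adjusted p = 0.299). They scored highest for macrophage markers, and the macrophage-like fall without overlap depends on leaving them out.

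**Figure D1:**
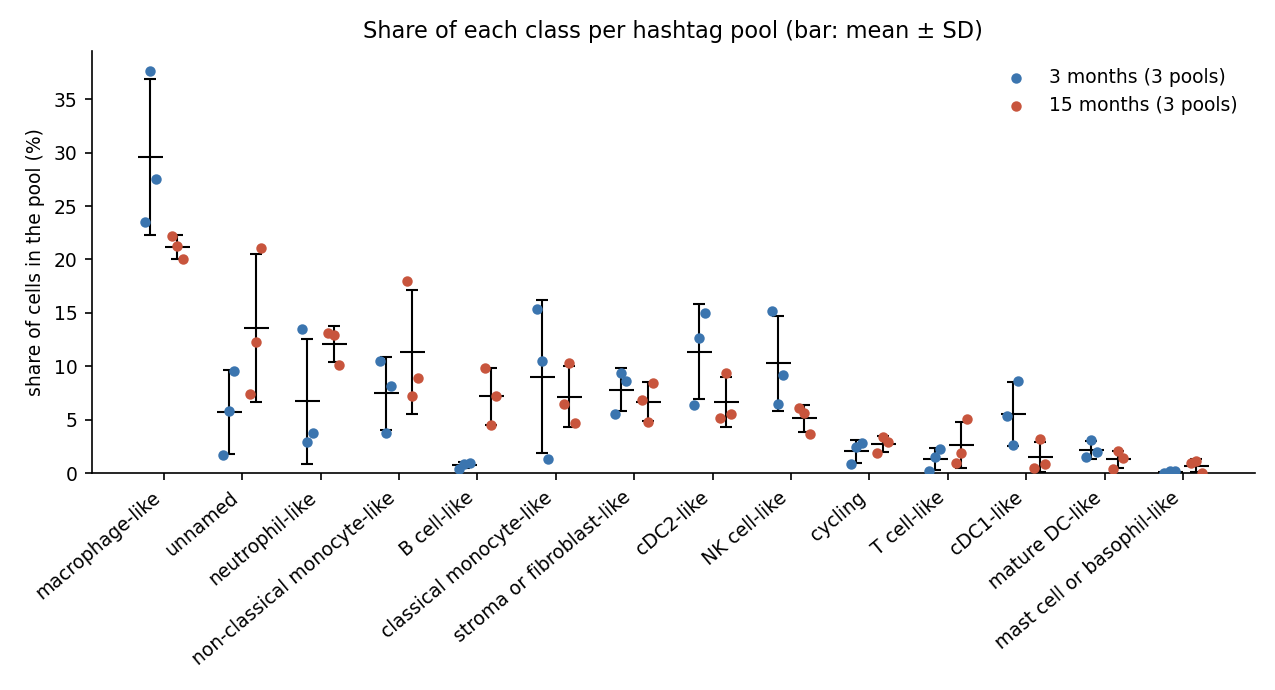
Share of kept cells in each class (percent, one point per hashtag pool, bar mean ± SD, 3 pools of each age). The B cell-like share is 0.765% at 3 months and 7.19% at 15 months on average, with no overlap between pools.

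Macrophage-like cells fell into 2 clusters. Cluster 2 (825 cells) scored highest for Lyve1 and Folr2 resident markers, and cluster 6 (518 cells) for the lipid-associated markers, with Spp1 at 4174 CPM against 63.3 CPM in cluster 2 and Fabp5 at 5060 against 221 CPM. Cluster 2 held 61.7 ± 18.2% of macrophage-like cells at 3 months and 58.0 ± 2.96% at 15 months (SD, n = 3 pools), with an edgeR adjusted p of 0.794, so the balance of the clusters differed by less than the spread between pools. The direction of this difference turned without the third 3-month pool, where cluster 2 had a log2 ratio of 0.22 and cluster 6 one of -0.27.

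Macrophage-like cells of the 15-month pools carried less Cdkn1a, the cell cycle inhibitor p21, and less haemoglobin RNA. They carried more Fcna, more Aig1 and more of 2 transcripts of one locus, Gm42418 and AY036118. Cdkn1a fell from 614 ± 91.1 to 220.5 ± 25.4 CPM (SD, n = 3 pools each), a log2 ratio of -1.47 ± 0.16 (SE, adjusted p = 0.00204), and was lower in every 15-month pool than in every 3-month pool. Fcna, which encodes the lectin ficolin A, rose from 9.78 ± 2.79 to 34.9 ± 4.599 CPM (log2 ratio 1.74, adjusted p = 0.0112). Aig1, which encodes an androgen-induced lipid hydrolase, rose from 13.5 ± 4.25 to 36.7 ± 2.74 CPM (log2 ratio 1.40, adjusted p = 0.0407). In all, 9 of 8512 genes passed the test, 4 higher and 5 lower at 15 months, while 918 had an unadjusted p under 0.05. Of all genes tested, 18.0% had no overlap between ages, where chance gives 10%.

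The other genes that passed belong to transcripts seen across cell classes. Hbb-bs, a beta globin of red blood cells, fell from 411 ± 109 to 10.85 ± 1.59 CPM (log2 ratio -5.21 ± 0.24, adjusted p = 1.84e-06), and Hba-a1, Hba-a2 and Hbb-bt had log2 ratios of -4.89, -4.99 and -4.10. The erythroid list had 4 measured members, all lower, 4 past the test over all genes and 4 adjusted over the list alone (camera adjusted p = 1.54e-15, adjusted p = 0.0898 with an estimated correlation). AY036118 rose from 93.8 ± 19.8 to 430.2 ± 52.5 CPM (log2 ratio 2.18 ± 0.18, adjusted p = 0.000187), and Gm42418 from 3023 ± 257 to 8946 ± 1204 CPM (log2 ratio 1.57 ± 0.14, adjusted p = 0.000315). These genes overlap on chromosome 17 on opposite strands (GRCm38), Gm42418 from 39846958 to 39848788 and AY036118 from 39847113 to 39848035. Cdkn1a lies on chromosome 17 from 29090976 to 29100727. Its log2 ratio ran from -1.59 to -1.06 over 23 alternatives, and its adjusted p passed 0.05 under the loose cell filter and Leiden resolution 0.3, with a highest value of 0.0784. The Fcna call ended under 11 of the 21 alternatives that measured it (highest adjusted p 0.427), with an adjusted p of 0.0738 and 0.0768 without 3-month pools 1 and 2 and 0.0644 without 15-month pool 2. The Aig1 call ended under 12 of 22 (highest adjusted p 0.343), with an adjusted p of 0.214 without 3-month pool 1 and 0.134, 0.179 and 0.0990 without 15-month pools 1, 2 and 3. The Gm42418 call ended under the loose cell filter (adjusted p = 0.0797). Genes past the test numbered 80 without the third 3-month pool, 14 without the second and 43 with DESeq2.

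**Figure D2:**
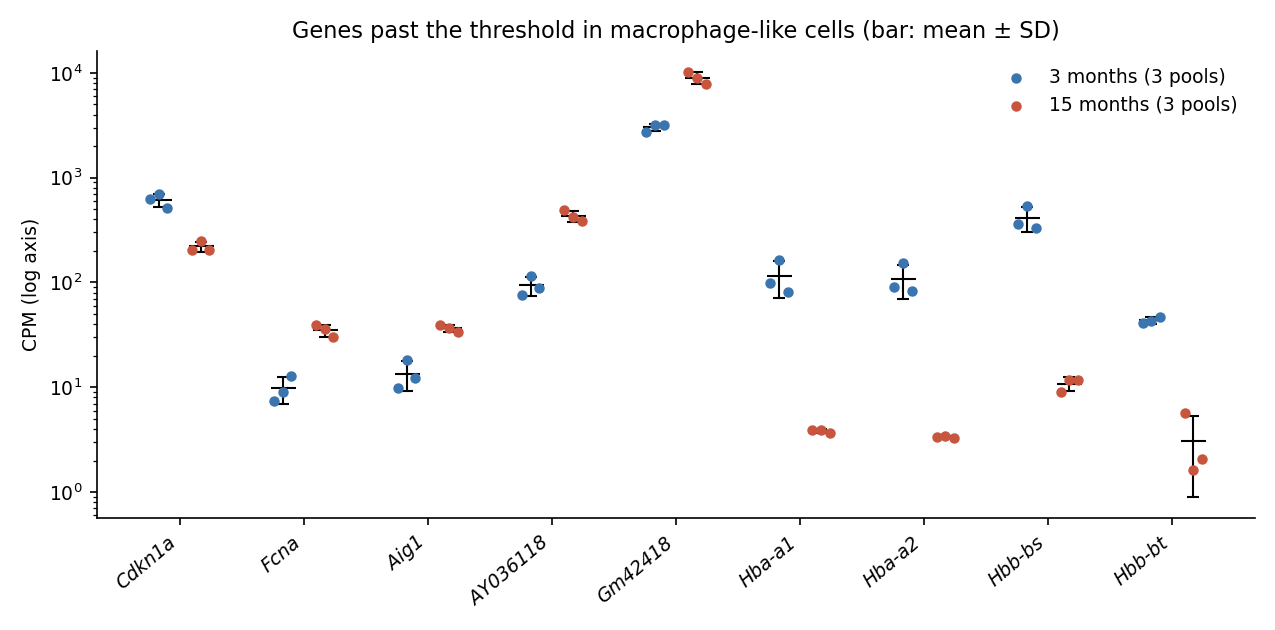
Levels in macrophage-like cells of the 9 genes past the edgeR threshold (CPM, log axis, one point per hashtag pool, bar mean ± SD, 3 pools of each age). Cdkn1a averages 614 CPM at 3 months and 220.5 CPM at 15 months, and no gene shown overlaps between ages.

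Groups of macrophage genes moved by smaller amounts, and 8 of the 22 lists measured in macrophage-like cells passed camera with its preset correlation. With an estimated correlation none did, so each adjusted p of that kind is given. The list of the immediate early and dissociation response fell as a set: 21 of 22 members had negative log2 ratios (mean -0.42), among them the early transcription factor Fos (3935 ± 497 to 2723 ± 71.7 CPM), Btg2 (1317 ± 265 to 745 ± 59.7 CPM) and Ier2 (477 ± 64.0 to 306 ± 52.3 CPM). None passed over all genes and 11 were lower adjusted over the list alone (camera adjusted p = 1.20e-06, adjusted p = 0.621 with an estimated correlation). The list of inflammatory cytokines and NF-kB targets also fell, with 13 of 17 members negative, such as Il1b, which encodes interleukin-1 beta (1425 ± 384 to 725 ± 103 CPM), and the endotoxin co-receptor gene Cd14 (1097 ± 25.3 to 723 ± 70.7 CPM). None passed over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0434, adjusted p = 0.621 with an estimated correlation). Cytosolic ribosomal protein genes fell by a small step, 67 of 86 negative with a mean log2 ratio of -0.14, none past over all genes and none adjusted over the list alone (camera adjusted p = 1.14e-05, adjusted p = 0.627 with an estimated correlation).

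Mitochondrial, lysosome, MHC class I and cell cycle lists rose in macrophage-like cells. Of the mitochondrially encoded transcripts 12 of 13 were positive, with mt-Co3 at 3924 ± 792 and 5932 ± 103 CPM. None passed over all genes and 7 adjusted over the list alone (camera adjusted p = 3.08e-06, adjusted p = 0.621 with an estimated correlation). The median mitochondrial share of all kept cells was 1.64 to 1.99% in 3-month pools and 2.24 to 2.71% in 15-month pools. A library difference is thus possible, as for haemoglobin. Of the lysosome genes 18 of 20 were positive, with the glycan-degrading enzyme gene Man2b1 at 209.5 ± 41.4 and 315 ± 26.9 CPM. None passed over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00358, adjusted p = 0.621 with an estimated correlation). Of the MHC class I genes 13 of 14 were positive, with their transactivator Nlrc5 at 5.46 ± 1.26 and 13.7 ± 3.12 CPM. Over all genes none passed, and 1 did adjusted over the list alone (camera adjusted p = 0.0118, adjusted p = 0.621 with an estimated correlation). All 14 measured cell cycle genes were positive, with Tk1 at 6.52 ± 2.32 and 20.9 ± 9.47 CPM and Mki67 at 8.61 ± 2.92 and 20.3 ± 5.87 CPM. Over all genes none passed, and 2 did adjusted over the list alone (camera adjusted p = 0.00244, adjusted p = 0.621 with an estimated correlation).

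Leaving out single pools ended some of these list calls in macrophage-like cells. The MHC class I list had an adjusted p of 0.137 without the second 15-month pool and 0.126 without the second 3-month pool, and the lysosome list 0.0657 without the first 15-month pool. The cell cycle list had 0.0608 without the first 3-month pool and 0.0999 without the third 15-month pool. The inflammatory list had 0.0839 without the first 3-month pool, 0.397 without the third 3-month pool and 0.438 without the third 15-month pool. The mitochondrial, ribosomal, immediate early and erythroid lists passed camera without each of the 6 pools in turn.

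**Figure D3:**
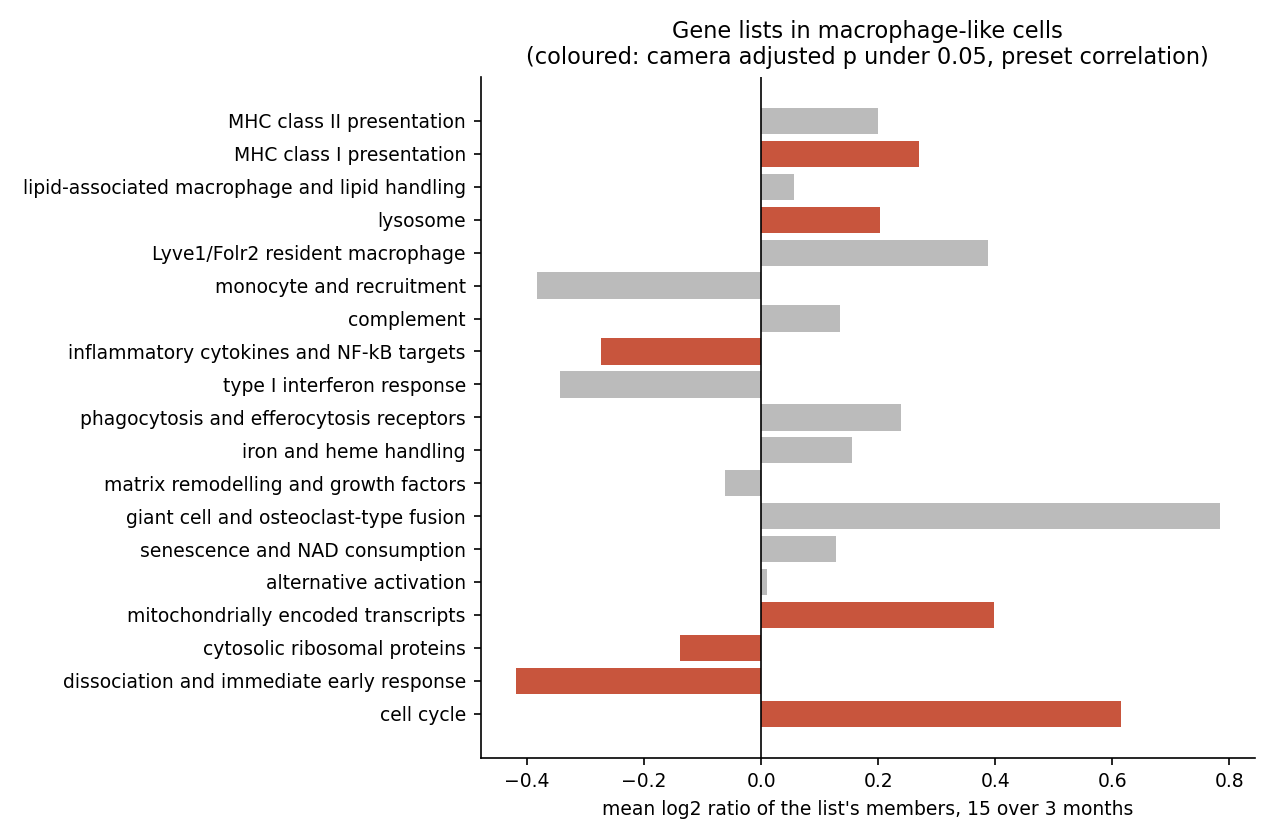
Mean log2 ratio (15 over 3 months) of the measured members of each list shown in macrophage-like cells, 3 pools of each age, with coloured bars for lists whose camera adjusted p was under 0.05. The immediate early and dissociation list averages -0.42 and the mitochondrial list 0.40.

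The remaining lists did not pass camera in macrophage-like cells. By fry in mixed directions the senescence and complement lists did (adjusted p = 0.00489 and 0.0122). The senescence list held the clearest single change, Cdkn1a, with 1 member past over all genes and 2 higher and 2 lower adjusted over the list alone. Gdf15, a stress cytokine gene of that list, stood at 425 ± 87.2 and 654 ± 149 CPM, and Plaur at 151 ± 46.1 and 89.9 ± 18.9 CPM. Complement genes had 3 higher and 2 lower adjusted over the list alone and none over all genes, with the receptor gene C5ar1 at 229.8 ± 12.98 and 160.4 ± 17.4 CPM. For the list of monocyte and recruitment genes, 10 of 14 members were negative, with the chemokine genes Ccl7 at 945 ± 551 and 206.5 ± 69.9 CPM and Ccl2 at 1268 ± 663 and 484 ± 182 CPM. None passed over all genes and 2 were lower adjusted over the list alone (camera adjusted p = 0.0842). For the list of type I interferon response genes, 16 of 19 were negative (camera adjusted p = 0.0509), with Irf7 at 54.0 ± 15.1 and 29.6 ± 8.06 CPM. For the fusion list, 7 of 8 were positive (camera adjusted p = 0.0605), with Acp5, the tartrate-resistant acid phosphatase gene, at 168 ± 23.3 and 347 ± 101 CPM.

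Of the further lists that did not pass, MHC class II genes had 7 of 8 members positive (camera adjusted p = 0.0812), with the transactivator Ciita at 48.3 ± 11.5 and 74.3 ± 4.22 CPM and 2 members higher adjusted over the list alone. Lipid handling genes had 11 of 16 positive (camera adjusted p = 0.295), with Gpnmb at 261 ± 179 and 637 ± 453 CPM and Plin2, a lipid droplet coat gene, at 1345 ± 499 and 890.1 ± 185 CPM. In cluster 2 alone the log2 ratios of both turned in sign, from 1.28 to -0.057 for Gpnmb and from -0.60 to 0.36 for Plin2, as did that of Plin2 at Leiden resolution 1.0 (0.24). Phagocytosis receptors had 7 of 14 positive (camera adjusted p = 0.2299), with Mertk, an apoptotic cell receptor gene, at 43.6 ± 4.91 and 79.0 ± 12.5 CPM and 1 member higher adjusted over the list alone. Iron and heme genes had 11 of 14 positive (camera adjusted p = 0.147), with Hpgds at 92.1 ± 25.0 and 154 ± 12.3 CPM and 2 higher adjusted over the list alone. The Lyve1 and Folr2 resident list (7 of 12 positive, camera adjusted p = 0.334) and the alternative activation list (8 of 11 positive, camera adjusted p = 0.708) did not pass, with Lyve1 at 2.57 ± 3.45 and 17.3 ± 15.9 CPM and the lectin gene Mgl2 at 419 ± 137 and 178 ± 84.5 CPM. The matrix list had camera's direction up with an adjusted p of 0.840, while its median and mean log2 ratios were -0.088 and -0.061, with Mmp14 at 56.2 ± 10.4 and 96.2 ± 4.26 CPM. Markers of neutrophils (4 of 4 positive, camera adjusted p = 0.0605) and of theca or luteal cells (2 of 4 positive, camera adjusted p = 0.708) did not pass in macrophage-like cells.

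The comparison in the other classes asked where else age went with a change. In cDC2-like cells, genes of the interferon and inflammatory response fell at 15 months. Cxcl10, an interferon-induced chemokine gene, fell from 728 ± 63.3 to 57.6 ± 57.5 CPM (SD, n = 3 pools each, log2 ratio -3.42 ± 0.46, adjusted p = 0.00390), and Ifit1, an interferon-induced antiviral gene, from 104 ± 32.2 to 15.6 ± 8.41 CPM (log2 ratio -3.03 ± 0.36, adjusted p = 0.00112). Il1a fell from 89.97 ± 33.7 to 25.0 ± 7.98 CPM (adjusted p = 0.00798), as did the chemokine gene Ccl4 from 2245 ± 716 to 849.8 ± 179 CPM (adjusted p = 0.0172). Osm, below the rule, fell by 1.30 on the log2 scale (adjusted p = 0.0416), a call that ended under 16 of 20 alternatives (highest adjusted p 0.597). Among these were DESeq2 (adjusted p = 0.0548), leaving out 3-month pools 1 and 3 (adjusted p = 0.1102 and 0.1137) and leaving out 15-month pools 1, 2 and 3 (adjusted p = 0.108, 0.243 and 0.1001). In all, 9 of 5219 genes passed, all lower, the other 4 being haemoglobin genes. All 18 measured interferon genes were negative, 2 past over all genes and 10 adjusted over the list alone (camera adjusted p = 2.01e-06, adjusted p = 0.640 with an estimated correlation). Of the inflammatory genes 13 of 17 were negative, 2 past over all genes and 5 adjusted over the list alone (camera adjusted p = 0.000496, adjusted p = 0.632 with an estimated correlation). The Cxcl10 call ended under 6 of 20 alternatives (highest adjusted p 0.2396). Its log2 ratio was -1.43 under the hashtag ratio rule, -2.02 with MULTIseqDemux, -1.745 with the strict cell filter, -1.74 without scrublet calls and -1.78 at Leiden resolution 1.0, and -3.395 (adjusted p = 0.0518) with a mean of at least 50 CPM. The Il1a call ended under 5 of 20, among them leaving out the second 15-month pool (adjusted p = 0.178) and the pool number as a block (adjusted p = 0.0594). The Ccl4 call ended under 9 of 20 (highest adjusted p 0.2335), among them without the first 3-month pool (adjusted p = 0.0650) and the second 15-month pool (adjusted p = 0.108). Ifit1 passed in all 15 alternatives that measured it. It was not measured where the Cxcl10 call ended, apart from the mean of at least 50 CPM. At Leiden resolution 1.0, 26 cells led by Isg15, Ifit3, Rsad2 and Cxcl10 formed a separate unnamed cluster. A fall within cDC2-like cells was thus not separated from the placing of such cells.

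Further lists passed camera in cDC2-like cells. The lipid handling list fell, with 14 of 14 members negative and none past over all genes or adjusted over the list alone (camera adjusted p = 0.0248, adjusted p = 0.640 with an estimated correlation). Cd36 stood at 110.0 ± 53.1 and 51.1 ± 38.9 CPM. The immediate early list fell, with 18 of 22 negative and none past by either adjustment (camera adjusted p = 0.0339, adjusted p = 0.640 with an estimated correlation). The mitochondrial list rose, with 11 of 12 positive, none past over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00328, adjusted p = 0.640 with an estimated correlation). The cell cycle list rose, with 10 of 10 positive, none past over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00189, adjusted p = 0.640 with an estimated correlation). Mcm5 stood at 15.1 ± 9.21 and 39.6 ± 5.64 CPM. The erythroid list fell with 4 of 4 members past (camera adjusted p = 2.03e-16, adjusted p = 0.0190 with an estimated correlation).

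Non-classical monocyte-like cells had 18 of 3932 genes past the test, 7 higher and 11 lower at 15 months. The heat shock gene Hspa1a fell from 734 ± 282 to 317 ± 86.9 CPM (SD, n = 3 pools each, log2 ratio -1.30 ± 0.22, adjusted p = 0.00512), and Hspa1b, below the rule, fell by 1.23 on the log2 scale. The immediate early and dissociation list that holds both did not pass (12 of 21 negative, camera adjusted p = 0.605). Psap, a lysosomal lipid-handling gene, rose from 1983 ± 269 to 2888 ± 384 CPM (adjusted p = 0.0425) and mt-Co3 from 2612 ± 259 to 4256 ± 676 CPM (adjusted p = 0.00346). AW112010 rose from 71.1 ± 20.2 to 227 ± 118 CPM (adjusted p = 0.0369), a call that ended under 9 of 20 alternatives. Among them, the adjusted p was 0.167, 0.0737 and 0.408 without 3-month pools 1, 2 and 3 in turn, and 0.145 without the second 15-month pool. Lars2, the mitochondrial leucyl-tRNA synthetase gene, rose from 58.7 ± 39.2 to 245.6 ± 25.6 CPM (adjusted p = 0.00164), with an adjusted p of 0.0503 without the third 3-month pool. Without the third 3-month pool the Hspa1a and Hspa1b calls ended (adjusted p = 0.235 and 0.245), the former also under Leiden resolution 0.3. The Psap call ended under 11 of 20 alternatives, among them without the first or the third 3-month pool (adjusted p = 0.312 and 0.367) and the second or the third 15-month pool (adjusted p = 0.0827 and 0.236). The AY036118 rise (log2 ratio 1.46, adjusted p = 0.0194) ended under 3 alternatives, among them leaving out the second or the third 3-month pool (adjusted p = 0.0692 and 0.367). DESeq2 gave Hba-a1 and Hba-a2 log2 ratios of -4.27 and -5.30 and no adjusted p. The count was 5 without the third 3-month pool and 69 without the first 15-month pool.

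By list, non-classical monocyte-like cells had 8 past camera, all but the erythroid list lost with an estimated correlation (adjusted p = 0.471 with an estimated correlation for each of these 7). The lysosome (17 of 19 positive, 1 past over all genes, 4 adjusted over the list alone), complement (7 of 8 positive, 1 past over all genes, 3 adjusted over the list alone) and mitochondrial lists (12 of 12 positive, 1 past over all genes, 9 adjusted over the list alone) rose, with camera adjusted p of 0.00789, 0.0259 and 8.71e-06. The inflammatory list rose here (11 of 11 positive, none over all genes, 1 adjusted over the list alone, camera adjusted p = 0.00175, adjusted p = 0.471 with an estimated correlation), with Nfkbiz at 262.5 ± 87.8 and 475 ± 108 CPM. The iron (8 of 9 positive, 3 adjusted over the list alone) and alternative activation (5 of 5 positive, 2 adjusted over the list alone) lists rose with camera adjusted p of 0.0174 and 0.0103, and none past over all genes (adjusted p = 0.471 with an estimated correlation). Ribosomal protein genes fell (69 of 82 negative, none over all genes, 11 adjusted over the list alone, camera adjusted p = 3.52e-05, adjusted p = 0.471 with an estimated correlation). The erythroid list fell with 4 of 4 past (camera adjusted p = 1.81e-15, adjusted p = 0.0202 with an estimated correlation).

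In NK cell-like cells S100a6, a calcium-binding protein gene, rose from 1091 ± 266 to 2368 ± 132 CPM (SD, n = 3 pools each, log2 ratio 1.09 ± 0.16, adjusted p = 0.00341), and Lars2 rose from 45.9 ± 15.3 to 226 ± 57.7 CPM (log2 ratio 2.17 ± 0.28, adjusted p = 0.00143). AY036118 and Gm42418 rose by log2 ratios of 2.81 and 2.56, while Hba-a1, Hba-a2 and Hbb-bs fell with log2 ratios of -4.77, -4.59 and -4.33, and Gm10076, below the rule, with one of -1.01. The Gm10076 call ended under 9 of 20 alternatives, with an adjusted p of 0.0524 by DESeq2 and 0.0539 with the pool number as a block. It was 0.0868 and 0.0940 without 3-month pools 1 and 3, and 0.135, 0.219 and 0.0978 without 15-month pools 1, 2 and 3. In all, 8 of 2705 genes passed the test. Without the second 15-month pool the calls of S100a6 and Hba-a2 ended, with an adjusted p of 0.0711 as the highest over 20 alternatives for each. DESeq2 gave Hba-a2 a log2 ratio of -3.92 and no adjusted p. Genes past the test numbered 17, 19 and 5 without 3-month pools 2 and 3 and 15-month pool 2. The mitochondrial list rose (10 of 12 positive, none over all genes, 2 adjusted over the list alone, camera adjusted p = 0.0144, adjusted p = 0.816 with an estimated correlation). The ribosomal list fell (68 of 78 negative, none past by either adjustment, camera adjusted p = 0.000127, adjusted p = 0.867 with an estimated correlation), and so did the erythroid list, with 3 of 3 members past (camera adjusted p = 2.33e-08, adjusted p = 0.102 with an estimated correlation). With the pool number as a block, for which the same-number pools of both ages correlated at 0.163, 0.149 and 0.119 across genes, 11 genes passed.

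Classical monocyte-like cells had 7 of 4136 genes past the test. Pirb, an inhibitory receptor gene, rose from 130 ± 7.18 to 357 ± 35.9 CPM (SD, n = 3 pools each, adjusted p = 0.0280), Ighm, the heavy chain of IgM, from 30.3 ± 13.1 to 138 ± 15.9 CPM (adjusted p = 0.0280) and AY036118 from 55.4 ± 30.4 to 333.9 ± 61.7 CPM (adjusted p = 0.0234). Ighm was positive in 5 of the 6 classes that measured it, beside the larger B cell-like share. Counted after the result was seen, its UMIs per classical monocyte-like cell were 0.252 and 1.003. Stroma or fibroblast-like (0.245 and 0.918) and macrophage-like cells (0.868 and 1.87) rose too, neutrophil-like (0.108 and 0.148) and NK cell-like cells (0.335 and 0.342) less so. Of the 318 in classical monocyte-like cells at 15 months 27 lay in cells with a Cd79a, Cd79b or Ms4a1 UMI. The part from B cell RNA or doublets was not estimated. Scimp, below the rule, fell by 2.71 on the log2 scale (adjusted p = 0.0280), a call that ended under 7 of the 13 alternatives that measured it (highest adjusted p 0.695). Its adjusted p was 0.374 and 0.173 without 3-month pools 1 and 2, and 0.0643 and 0.187 without 15-month pools 1 and 3. Hbb-bs, Hba-a2 and Hba-a1 fell with log2 ratios of -4.45, -4.23 and -3.73. The mitochondrial list rose (12 of 12 positive, none over all genes, 8 adjusted over the list alone, camera adjusted p = 0.000412, adjusted p = 0.325 with an estimated correlation), and the erythroid list fell with 3 of 3 past (camera adjusted p = 5.49e-08, adjusted p = 0.0802 with an estimated correlation). The pools differed in make-up: cluster 5 gave 56, 35 and 0 cells in the 3-month pools and 2, 75 and 6 in the 15-month pools, and cluster 10 gave 16, 12 and 12 against 46, 152 and 36. The number of genes past the test was 2 without the first 3-month pool and 917 without the third. It was 3, 16 and 3 without 15-month pools 1, 2 and 3 in turn. The Pirb and Ighm calls each ended under 9 of 16 alternatives and the AY036118 call under 6. For Pirb the adjusted p was 0.281 and 0.267 without 3-month pools 1 and 2, and 0.104 and 0.192 without 15-month pools 1 and 3. For Ighm it was 0.281, 0.267, 0.0778 and 0.177 without the same pools. For AY036118 it was 0.281 without 3-month pool 1, and 0.0643 and 0.153 without 15-month pools 1 and 3. With the pool number as a block the calls of Pirb, Ighm, AY036118 and Scimp ended (adjusted p = 0.148 for each) and only the 3 haemoglobin genes passed. The Hba-a2 call ended without 3-month pool 1 (adjusted p = 0.106), and DESeq2 gave this gene a log2 ratio of -4.24 and no adjusted p.

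Neutrophil-like cells had 4 of 1955 genes past the test: Hbb-bs, Hba-a1 and Hba-a2 fell with log2 ratios of -4.21, -4.29 and -4.93, and Gm42418, below the rule, rose by a log2 ratio of 1.98. The Gm42418 call ended without the first 3-month pool (adjusted p = 0.127) and the first 15-month pool (adjusted p = 0.0517). The erythroid list fell with 3 of 3 members past (camera adjusted p = 3.26e-14, adjusted p = 0.0227 with an estimated correlation), and no other list passed in these cells.

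In stroma or fibroblast-like cells the lipoprotein lipase gene Lpl rose from 37.8 ± 2.75 to 149.6 ± 39.8 CPM (SD, n = 3 pools each, log2 ratio 1.99 ± 0.25, adjusted p = 0.0348) and the long noncoding AW112010 from 40.1 ± 5.47 to 161 ± 46.3 CPM (log2 ratio 2.04 ± 0.27, adjusted p = 0.0447). Hba-a2, Hbb-bs, Hbb-bt and, below the rule, Hba-a1 fell with log2 ratios of -4.46, -4.14, -3.56 and -3.43, which made 6 genes past the test of 8867. MHC class I genes rose as a set, 13 of 13 positive with none past over all genes and 13 adjusted over the list alone (camera adjusted p = 6.50e-11, adjusted p = 0.398 with an estimated correlation). The immunoproteasome gene Psmb9 stood at 51.0 ± 10.2 and 121 ± 21.9 CPM. Complement genes rose (10 of 11 positive, none over all genes, 4 adjusted over the list alone, camera adjusted p = 3.52e-05, adjusted p = 0.398 with an estimated correlation), with C3 at 12.8 ± 7.94 and 137 ± 82.5 CPM. Interferon genes rose (15 of 16 positive, none over all genes, 6 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.99e-05, adjusted p = 0.398 with an estimated correlation). The Lpl call ended under 8 of 20 alternatives and the AW112010 call under 10 of 20. Without 3-month pools 1, 2 and 3 in turn the adjusted p of Lpl was 0.182, 0.195 and 0.140, and that of AW112010 was 0.182, 0.206 and 0.159. Without the first 15-month pool that of AW112010 was 0.0568. The Hba-a1 call ended under 11 of the 19 alternatives that measured it, with an adjusted p of 0.182, 0.206 and 0.0747 without 3-month pools 1, 2 and 3 and 0.0533 and 0.0988 without 15-month pools 1 and 3. The Hba-a2 call ended without 3-month pools 2 and 3 (adjusted p = 0.0714 and 0.0508). The Hbb-bt call ended without 3-month pools 1, 2 and 3 (adjusted p = 0.142, 0.0737 and 0.140) and 15-month pool 3 (adjusted p = 0.0820). The count was 2, 1 and 2 without 3-month pools 1, 2 and 3 in turn and 31 without the second 15-month pool.

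More lists passed camera in stroma or fibroblast-like cells, where markers of other cell types moved too. At Leiden resolution 1.0, 234 cells had this name, beside 63 endothelial-like, 36 theca or luteal-like and 45 unnamed cells scoring highest for epithelial markers. A change in make-up was thus not separated from changes within cells for Lpl, AW112010 or the lists. At 15 months these cells held 37.1 UMIs per cell of the myeloid genes Tyrobp, Fcer1g and Csf1r, 41.9% of the macrophage-like level, so changes in the lists of myeloid functions are not shown to be those of stroma. Granulosa markers fell (8 of 9 negative, none over all genes, 5 adjusted over the list alone, camera adjusted p = 1.54e-05, adjusted p = 0.398 with an estimated correlation), with the hormone gene Amh at 61.9 ± 64.1 and 0.512 ± 0.887 CPM. Theca or luteal markers fell (6 of 7 negative, none over all genes, 1 adjusted over the list alone, camera adjusted p = 0.00739, adjusted p = 0.485 with an estimated correlation), with Lhcgr, the luteinizing hormone receptor gene, at 109.6 ± 102 and 15.3 ± 8.78 CPM. Epithelial markers rose (8 of 8 positive, none over all genes, 5 adjusted over the list alone, camera adjusted p = 0.000459, adjusted p = 0.485 with an estimated correlation), with the keratin gene Krt19 at 26.1 ± 22.3 and 171.5 ± 38.4 CPM. B cell markers rose (3 of 3 positive, none over all genes, 2 adjusted over the list alone, camera adjusted p = 0.00681, adjusted p = 0.398 with an estimated correlation), with Ighm at 15.1 ± 4.32 and 50.4 ± 15.9 CPM. Lists of MHC class II (8 of 8 positive), lipid handling (14 of 15) and lysosome genes (18 of 19) rose, with camera adjusted p of 0.000622, 0.000459 and 0.000121 (adjusted p = 0.485 with an estimated correlation). Lists of phagocytosis (12 of 13 positive) and senescence genes (10 of 11) rose with camera adjusted p of 0.000636 and 0.0265 (adjusted p = 0.398 and 0.485 with an estimated correlation). Among these 5 lists, Lpl alone passed over all genes. Adjusted over the list alone there were 0, 1, 6, 3 and 0 higher in this order, and in the lysosome list 1 lower. The ribosomal (72 of 84 negative, 8 adjusted over the list alone) and immediate early lists (16 of 22 negative, 4 adjusted over the list alone) fell with camera adjusted p of 1.78e-06 and 0.0469 and none past over all genes (adjusted p = 0.493 with an estimated correlation). The erythroid list fell with 4 of 4 past (camera adjusted p = 2.16e-11, adjusted p = 0.0494 with an estimated correlation).

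Across the 7 classes tested, 8 genes passed in at least 2 classes and 24 in exactly 1. Hba-a1, Hba-a2 and Hbb-bs passed in all 7, with log2 ratios from -5.21 to -3.43. AY036118 and Gm42418 were positive in all 7 and passed in 4 each, and Lars2 was positive in all 7 and passed in 2. Cdkn1a passed in macrophage-like cells, was negative in 6 of 7 classes, and was 0.080 on the log2 scale in stroma or fibroblast-like cells. The difference between macrophage-like and neutrophil-like cells in this ratio was -1.35 ± 0.47 (SE, edgeR adjusted p = 0.332) and did not pass, and differences from the other classes were not tested.

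Over all kept cells together, which mixes make-up with expression, genes of B cells and transcripts of the Gm42418 locus rose. AY036118 rose from 89.6 ± 21.4 to 359.8 ± 42.5 CPM (SD, n = 3 pools each, adjusted p = 0.0230) and Lars2 from 58.4 ± 1.08 to 146 ± 23.8 CPM (adjusted p = 0.02965). Below the rule, the immunoglobulin gene Iglc3 and the B cell chemokine receptor gene Cxcr5 rose by log2 ratios of 2.95 and 3.38, and Gm42418, Tsix and C130026I21Rik by 1.60, 1.26 and 2.05, making 7 of 11882 genes, all higher. The B cell list rose with 10 of 10 positive, none past over all genes and 10 adjusted over the list alone (camera adjusted p = 7.68e-12, adjusted p = 0.410 with an estimated correlation), with Cd79a, a B cell receptor subunit gene, at 15.7 ± 3.80 and 109.9 ± 50.6 CPM. NK cell markers fell (10 of 10 negative, none past by either adjustment, camera adjusted p = 0.00320, adjusted p = 0.701 with an estimated correlation), and neutrophil markers rose (9 of 10 positive, none past by either adjustment, camera adjusted p = 0.00409, adjusted p = 0.701 with an estimated correlation). The senescence list rose (10 of 13 positive, none over all genes, 6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0270, adjusted p = 0.410 with an estimated correlation), with the NAD-consuming enzyme gene Cd38 at 28.5 ± 2.01 and 52.1 ± 6.45 CPM and Cdkn2a at 0.5999 ± 0.658 and 11.8 ± 9.51 CPM, while Cdkn1a stood at 483 ± 51.1 and 240.8 ± 49.3 CPM. The AY036118 call ended without 3-month pools 1 and 3 (adjusted p = 0.131 and 0.0676) and 15-month pools 1 and 3 (adjusted p = 0.0581 and 0.0706). The Lars2 call ended without 3-month pools 1, 2 and 3 (adjusted p = 0.131, 0.152 and 0.0805) and 15-month pool 3 (adjusted p = 0.0706). The Iglc3, Cxcr5, Gm42418, Tsix and C130026I21Rik calls ended under 4 of 17, 6 of 17, 5 of 18, 6 of 17 and 7 of 17 alternatives that measured them. In this order of genes, the adjusted p was 0.131 for each without 3-month pool 1, 0.136, 0.136, 0.0811, 0.126 and 0.161 without pool 2, and 0.0676, 0.0805, 0.0676, 0.0676 and 0.0805 without pool 3. It was 0.0582, 0.1095, 0.0706, 0.0706 and 0.0706 without 15-month pool 3, and 0.0879, 0.0547 and 0.0623 for Cxcr5, Tsix and C130026I21Rik without 15-month pool 1. With the pool number as a block 7 genes passed, 2 of them the same. The calls of AY036118, Lars2, Gm42418, Tsix and Cxcr5 ended there (adjusted p = 0.0657, 0.0564, 0.0719, 0.0719 and 0.0902). With edgeR the count of 7 went to 0, 1 and 0 without 3-month pools 1, 2 and 3 in turn. It went to 23 without the second 15-month pool and to 0 without the third, and DESeq2 gave 249 genes.

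Other lists also passed camera over all kept cells. Granulosa (9 of 9 negative, 3 adjusted over the list alone), theca or luteal (5 of 7 negative, 2 adjusted over the list alone) and erythroid markers (5 of 5 negative, 5 adjusted over the list alone) fell, with camera adjusted p of 5.88e-05, 0.0270 and 8.61e-08 and none past over all genes (adjusted p = 0.410, 0.701 and 0.410 with an estimated correlation). Epithelial markers rose (8 of 8 positive, none over all genes, 3 adjusted over the list alone, camera adjusted p = 0.00512, adjusted p = 0.701 with an estimated correlation). The mitochondrial (12 of 13 positive, 7 adjusted over the list alone), lysosome (16 of 20 positive, 2 adjusted over the list alone) and cell cycle lists (17 of 18 positive, 0 adjusted over the list alone) rose, with camera adjusted p of 5.12e-05, 0.0375 and 0.0351 and none past over all genes (adjusted p = 0.701, 0.701 and 0.831 with an estimated correlation). The ribosomal (75 of 88 negative, 0 adjusted over the list alone), immediate early (18 of 22 negative, 4 adjusted over the list alone) and interferon lists (13 of 20 negative, 1 adjusted over the list alone) fell, with camera adjusted p of 2.45e-07, 0.00308 and 0.0375 and none past over all genes (adjusted p = 0.701, 0.701 and 0.831 with an estimated correlation).

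The last comparison asked whether the age effect differed between macrophage-like cells and the next largest class tested, the neutrophil-like cells. Of 7034 genes, 5 differed, all with a lower age effect in macrophage-like cells, and 716 had an unadjusted p under 0.05. Cxcl10 had a difference of log2 ratios of -5.57 ± 0.98 (SE, adjusted p = 8.95e-05). Over summed pools it had 78.9 CPM at 3 months and 51.1 at 15 months in macrophage-like cells (366 and 524 UMIs). Neutrophil-like cells had 4.73 and 240 CPM (1 and 264 UMIs, 255 of the latter in the second 15-month pool). Neutrophil-like cells joined clusters 8 and 17, and cluster 17 gave 9, 2 and 0 cells in the 3-month pools and 6, 107 and 8 in the 15-month pools, so a change in make-up was not separated from a change within cells. The gene of tumour necrosis factor, Tnf, had a difference of -2.21 ± 0.48 (adjusted p = 0.00849), with 66.9 and 68.0 CPM against 147 and 502 (310 and 698 UMIs against 31 and 553). AA467197 and F630028O10Rik had differences of -2.21 and -2.35 (adjusted p = 0.00849 and 0.0347), and Dnajc3 one of -9.34 (adjusted p = 0.0347) that is no bound, since neutrophil-like cells had 0 UMIs at 3 months and 56 at 15 months. The count was 13 without 3-month pool 2, and 1 and 2 without 15-month pools 2 and 3. It was 3 with RLE factors and 0 with a mean of at least 50 CPM.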

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

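The tests of free RNA, of the sort and of the libraries, and the splits of the pools, were chosen after the result was seen, whereas the test of droplets holding 2 cells and the interaction test were set before. In the test of the sort, the condition on myeloid RNA in stroma or fibroblast-like cells was added once the value of that test was known, and without it the test would have counted against the sort.

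Haemoglobin transcripts were lower at 15 months in each of the 7 classes tested, and 689 of 3135 barcodes at 3 months and 51 of 4939 at 15 months had over 50% haemoglobin UMIs, 559 and 50 of these called negative for hashtags. Red blood cell RNA free in the 3-month suspension is a candidate explanation: Hba-a1, Hba-a2 and Hbb-bs UMIs per cell lay between 2.76 and 5.35 in these classes while mean UMIs per cell ran from 1903 to 14633. An even level did not hold in every class: 20 of 116 cDC1-like cells at 3 months, a class too small to test, had over 1% haemoglobin UMIs, and the class had a mean of 1230.7 such UMIs per cell and 4.917 without those cells. Within the 3-month library the ratio of Hba-a1 plus Hba-a2 to Hbb-bs was 0.636 in the mostly haemoglobin barcodes and 0.416 to 0.548 in the classes, a largest departure of 1.528 times, just over the 1.5 set for this explanation and under the 3 set against it, so the test leaves it open. A difference between the libraries other than age cannot be told apart from age with 1 library per age, and an effect of age itself was not tested.

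Gm42418, AY036118 and Lars2 had positive log2 ratios in each of the 7 classes tested. RNA free in the 15-month suspension would add like numbers of Gm42418 UMIs to every class, but these were 23.1 to 137.4 per cell, a ratio of 5.947, which argues against it as the whole cause. With 1 library per age, a difference between the libraries other than age cannot be told apart from age. An effect of age itself was not tested, and both may contribute.

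The share of B cell-like cells was larger at 15 months among cells sorted by CD11b. At 15 months Itgam, the gene of CD11b, stood at 77.2 CPM (of all UMIs of the class) in B cell-like cells. It stood at 112 CPM in macrophage-like, 118 in T cell-like, 229 in NK cell-like and 32.9 in stroma or fibroblast-like cells. The RNA thus gives no ground to expect B cell-like cells outside the gate, and CD11b protein was not measured here. Droplets holding a B cell and a sorted myeloid cell would carry myeloid RNA, but Tyrobp, Fcer1g and Csf1r UMIs in B cell-like cells were 6.784% of the macrophage-like level, which argues against this. A sort that let through more cells of all other types would raise stroma or fibroblast-like cells as well, and the log2 ratio of the B cell-like share exceeded theirs by 3.396 ± 0.88 (SE). That does not exclude it, since stroma or fibroblast-like cells held 41.9% of the macrophage-like level of these myeloid genes and may have been sorted with myeloid cells. The sort, or another difference between the libraries, cannot be told apart from age with 1 library per age, and more B cells in the older ovary may be the reason but was not tested.

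The age effect differed between macrophage-like and neutrophil-like cells in 5 genes by an interaction test. The differences of log2 ratios were -5.566 for Cxcl10, -2.209 for AA467197, -2.212 for Tnf, -9.343 for Dnajc3 and -2.348 for F630028O10Rik. Of the 264 Cxcl10 UMIs in neutrophil-like cells at 15 months, 255 came from the second pool, which also gave 441 of the 608 AA467197 UMIs. Cluster 17, 1 of the 2 clusters of neutrophil-like cells, gave 107 of its 121 cells at 15 months in that pool, so a change in make-up was not separated from a change within cells. The value for Dnajc3 is no bound, since neutrophil-like cells had 0 of its UMIs at 3 months and 56 at 15 months.

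The 6 pools can be split into 3 and 3 in 10 ways, too few for a share under 0.05, so this count decides nothing for any class. For macrophage-like cells 2 of the 10 splits gave as many genes (real split 9, highest other 18), for classical monocyte-like cells 2 (7 and 58) and for neutrophil-like cells 2 (4 and 8). The real split alone gave as many, 1 of 10, for NK cell-like (8, highest other 4), cDC2-like (9 and 3), non-classical monocyte-like (18 and 12) and stroma or fibroblast-like cells (6 and 0), and for all kept cells (7 and 0). For the difference between classes 3 of the 10 gave as many (5 and 7). The split with 58 genes set 3-month pools 1 and 2 with the second 15-month pool, which are the 3 pools with 35 or more cells of cluster 5, and so points to the make-up of the pools.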

How the results depend on the processing

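The wider macrophage class, clusters 2 and 6 alone and cells under 1% haemoglobin UMIs were tests chosen after the result was seen, and the other alternatives were set before. Over all results and alternatives, the counts of genes and lists and the shares of classes and clusters kept direction and side of the threshold, or stayed within 1.5 times, in 355 cases. They moved further in 102, turned in direction in 25, passed the threshold newly in 6 and no longer passed in 2. For named genes the same held in 4991 cases, with 257 newly past the threshold, 118 no longer past it and 46 turned in direction, and for single lists in 196, with 23, 31 and 11. Hbb-bs passed in each of the 7 classes under every alternative run, with log2 ratios from -6.18 to -3.78. The larger share of B cell-like cells had log2 ratios from 2.87 to 3.42 over 16 alternatives and passed in 14. A gene that DESeq2 gave no adjusted p, as with Hba-a2 in NK cell-like cells, was counted as no longer past the threshold.

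With DESeq2, the count of genes past the test was 43 for macrophage-like, 16 for NK cell-like and 14 for cDC2-like cells. It was 64 for classical monocyte-like, 84 for stroma or fibroblast-like and 249 for all kept cells. With no low-count filter, it was 254 for macrophage-like, 86 for NK cell-like, 118 for cDC2-like and 605 for classical monocyte-like cells. It was 14 for neutrophil-like, 50 for non-classical monocyte-like, 129 for stroma or fibroblast-like and 75 for all kept cells. With pool number as a block, it was 24 for macrophage-like, 3 for classical monocyte-like and 29 for stroma or fibroblast-like cells. Log2 ratios turned in sign, 0.019 for Ooep (all kept cells). The direction of the set test turned, with mean log2 ratios of -0.066 for the matrix remodelling and growth factors list (macrophage-like cells). The share ratio now passed, -1.98 for cDC1-like. Log2 ratios of shares turned in sign, 0.10 for classical monocyte-like. With MULTIseqDemux, 15 genes passed for macrophage-like, 27 for NK cell-like and 24 for all kept cells. Log2 ratios turned in sign for H2-DMa (-0.060), H2-T23 (-0.15), Arg1 (0.43) and Mmp9 (-0.75) in macrophage-like cells. They also turned for Tnf (0.26, cDC2-like), C1qa (-0.049, non-classical monocyte-like), and Serpine2 and Ebf1 (0.88 and -0.69, stroma or fibroblast-like). Shares had log2 ratios of turned sign, 0.47 for classical monocyte-like, 0.66 for stroma or fibroblast-like, 0.17 for cluster 2 and -0.34 for cluster 6. With the loose cell filter, 5 genes passed for macrophage-like, 23 for NK cell-like, 12 each for classical monocyte-like and stroma or fibroblast-like, and 38 for all kept cells. Log2 ratios turned in sign, -0.068 for Ebf1 (stroma or fibroblast-like cells). Shares had log2 ratios of turned sign, 1.34 for classical monocyte-like, 0.035 for stroma or fibroblast-like, 0.31 for cluster 2 and -0.36 for cluster 6. With the wider macrophage class, 15 genes passed. In cluster 2 alone, 17 genes passed. Log2 ratios turned in sign for H2-T23 (-0.026), Gpnmb (-0.057), Plin2 (0.36), Ccl5 (0.16), Mmp12 (2.73), Ccl24 (-0.64) and Mmp9 (-0.39). At Leiden resolution 1.0, log2 ratios turned in sign for Plin2 (0.24), Arg1 (0.51), S100a8 (-0.35), Mmp9 (-0.59) and S100a9 (-0.90) in macrophage-like cells. They also turned for Serpine2 and Ebf1 in stroma or fibroblast-like cells (0.0021 and -0.15). In NK cell-like cells 15 genes passed, and in stroma or fibroblast-like cells 2. The share ratio now passed, -1.76 for cDC1-like. Shares had log2 ratios of turned sign, 1.22 for classical monocyte-like and 0.079 for stroma or fibroblast-like. With the strict cell filter, log2 ratios turned in sign for Ifit3 (0.018) and Hsd3b1 (0.11) in macrophage-like cells. Genes past the test were 37 for NK cell-like, 25 for stroma or fibroblast-like and 13 for all kept cells. The share ratio now passed, -1.70 for cDC1-like and 3.24 for neutrophil-like. Log2 ratios of shares turned in sign, 1.20 for classical monocyte-like, 0.35 for cluster 2 and -0.39 for cluster 6. In cluster 6 alone, log2 ratios turned in sign for Cyp11a1 (0.63) and S100a9 (-0.075). With the hashtag ratio rule, log2 ratios turned in sign for Hsd3b1 (0.19) in macrophage-like cells. In non-classical monocyte-like cells they turned for C1qb (-0.64), C1qa (-0.13), Fth1 (-0.16) and Ftl1 (-0.15). Genes past the test were 25 for NK cell-like, 20 for stroma or fibroblast-like and 27 for all kept cells. Shares had log2 ratios of turned sign, 0.93 for classical monocyte-like, 0.031 for stroma or fibroblast-like, 0.30 for cluster 2 and -0.32 for cluster 6. With the deeper library thinned, log2 ratios turned in sign, 0.0052 for Hsd3b1 (macrophage-like cells). With scrublet calls removed, the count of genes past the test was 26 for NK cell-like cells. Shares had log2 ratios of turned sign, 0.071 for cluster 2 and -0.15 for cluster 6. At Leiden resolution 0.3, the count of genes past the test was 24 for NK cell-like cells and 14 for cDC2-like cells. With a mean of at least 50 CPM, 2 genes passed for cDC2-like, 4 for classical monocyte-like and 1 for stroma or fibroblast-like cells. The set test turned in direction in macrophage-like cells for 2 lists. Mean log2 ratios were -0.27 for matrix remodelling and growth factors and -0.21 for senescence and NAD consumption. Lists past the test were 4 for cDC2-like, 1 for classical monocyte-like and 5 for all kept cells. The count of genes past the test was 0 for the difference between classes. In cells under 1% haemoglobin UMIs, log2 ratios turned in sign, -0.0080 for Fth1 (non-classical monocyte-like cells). The count of genes past the test was 30 for all kept cells. Shares had log2 ratios of turned sign, 0.21 for cluster 2 and -0.27 for cluster 6. With camera using an estimated correlation, 1 list passed in each of cDC2-like, non-classical monocyte-like and stroma or fibroblast-like cells. The number was 0 for macrophage-like, NK cell-like, classical monocyte-like and all kept cells. With fry in 1 direction, it was 1 for macrophage-like, NK cell-like, cDC2-like, non-classical monocyte-like and stroma or fibroblast-like cells, and 0 for all kept cells. With fry in mixed directions, 3 lists passed for macrophage-like, 3 for cDC2-like, 0 for neutrophil-like, 5 for stroma or fibroblast-like and 9 for all kept cells. With RLE factors, the count of genes past the test was 3 for the difference between classes. By exact permutation of pool shares, the share ratio no longer passed, 3.23 for B cell-like (exact p = 0.1, the smallest that 3 against 3 pools allow, adjusted p = 0.467).

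Leaving out each pool in turn, counts of genes ran as follows: macrophage-like cells from 7 to 80 (14 without 3-month pool 2 and 80 without 3-month pool 3), NK cell-like cells from 5 to 19 (17 without 3-month pool 2, 19 without 3-month pool 3 and 5 without 15-month pool 2), cDC2-like cells from 6 to 21 (21 without 3-month pool 2 and 15 without 3-month pool 3) and classical monocyte-like cells from 2 to 917 (2 without 3-month pool 1, 917 without 3-month pool 3, 3 without 15-month pool 1, 16 without 15-month pool 2 and 3 without 15-month pool 3). For non-classical monocyte-like cells from 5 to 69 (5 without 3-month pool 3 and 69 without 15-month pool 1), stroma or fibroblast-like cells from 1 to 31 (2 without 3-month pool 1, 1 without 3-month pool 2, 2 without 3-month pool 3 and 31 without 15-month pool 2) and all kept cells from 0 to 23 (0 without 3-month pool 1, 1 without 3-month pool 2, 0 without 3-month pool 3, 23 without 15-month pool 2 and 0 without 15-month pool 3). For the difference between classes from 1 to 13 (13 without 3-month pool 2, 1 without 15-month pool 2 and 2 without 15-month pool 3). Numbers of lists past the test ran: NK cell-like cells from 2 to 5 (5 without 3-month pool 2 and 5 without 3-month pool 3), classical monocyte-like cells from 2 to 5 (4 without 3-month pool 2, 5 without 3-month pool 3, 4 without 15-month pool 1 and 4 without 15-month pool 3), neutrophil-like cells from 1 to 2 (2 without 15-month pool 1, 2 without 15-month pool 2 and 2 without 15-month pool 3) and non-classical monocyte-like cells from 4 to 9 (4 without 3-month pool 1 and 5 without 3-month pool 3). Log2 ratios of named genes, turned in sign where a pool is named, ran as follows in macrophage-like cells. Igf1 ran from -0.72 to 0.050 (0.050 without 3-month pool 2) and Ccl5 from -2.07 to 1.12 (1.12 without 3-month pool 3). Ctsk ran from -0.75 to 2.43 (-0.75 without 15-month pool 3) and Cyp11a1 from -0.45 to 0.0063 (0.0063 without 3-month pool 3). Hsd3b1 ran from -0.31 to 0.19 (0.17 without 3-month pool 3 and 0.19 without 15-month pool 3). S100a9 ran from -0.31 to 1.87 (-0.31 without 15-month pool 2). In stroma or fibroblast-like cells Ebf1 ran from -0.19 to 0.63 (-0.19 without 3-month pool 1 and -0.067 without 15-month pool 3). Over all kept cells Ooep ran from -1.10 to 2.36 (2.36 without 3-month pool 3 and 0.28 without 15-month pool 2). Mean log2 ratios of lists in macrophage-like cells, with the set test turned in direction where a pool is named, ran as follows. The lipid-associated macrophage and lipid handling list ran from -0.28 to 0.36 (-0.16 without 3-month pool 3 and -0.28 without 15-month pool 1). The Lyve1/Folr2 resident macrophage list ran from 0.24 to 0.82 (0.24 without 3-month pool 1). The matrix remodelling and growth factors list ran from -0.26 to 0.20 (-0.26 without 3-month pool 3 and -0.20 without 15-month pool 1). The alternative activation list ran from -0.19 to 0.40 (-0.19 without 3-month pool 3). The theca or luteal (steroidogenic) list ran from -0.075 to 0.32 (-0.055 without 3-month pool 1 and -0.030 without 15-month pool 1). Log2 ratios of shares, changed in sign or in passing the test where a pool is named, ran: B cell-like from 2.87 to 3.42 (3.25 without 3-month pool 2), cDC1-like from -2.92 to -1.29 (-2.92 without 15-month pool 2), classical monocyte-like from -0.84 to 0.34 (0.34 without 3-month pool 1) and neutrophil-like from 0.50 to 1.83 (1.83 without 3-month pool 1). For cluster 2 from -0.29 to 0.22 (0.22 without 3-month pool 3) and cluster 6 from -0.27 to 0.57 (-0.27 without 3-month pool 3).

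Without a pool, 3 pools of 1 age are set against 2 of the other, and counts of genes both rose and fell. For the changes above, the cause was not tested. The classical monocyte-like class could not be tested under the hashtag ratio rule, the strict cell filter, removal of scrublet calls and Leiden resolution 0.3, nor the neutrophil-like class under the strict cell filter, where the class was absent or had too few cells in a pool. Removal of scrublet calls changed the clustering.

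Some lists passed fry in mixed directions and not camera. They were the senescence and complement lists in macrophage-like cells (adjusted p = 0.00489 and 0.0122), MHC class I and interferon in NK cell-like cells (0.00113 and 0.0289) and alternative activation in cDC2-like cells (0.0390). The others were senescence and immediate early in non-classical monocyte-like cells (0.0293 and 0.0164), and iron and plasma cell lists over all kept cells (6.38e-05 and 0.0447).

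Depth and spread limit the tests. In simulated counts, 2-fold changes were found for 88.06% of changed genes in macrophage-like cells, 70.15% in cDC2-like and in non-classical monocyte-like cells and 54.1% in NK cell-like cells. In stroma or fibroblast-like, classical monocyte-like and neutrophil-like cells the shares were 29.85%, 25.76% and 6.78%, and for the difference between classes 2.985%. A gene not past the test is no sign of equal levels. Only genes of at least 50 CPM were changed, and macrophage-like calls were 146 against 9 in the data. False calls in the simulated counts were 13 of 139 in cDC2-like, 11 of 135 in non-classical monocyte-like and 8 of 106 in NK cell-like cells. They were 8 of 146 in macrophage-like, 6 of 85 in classical monocyte-like, 2 of 63 in neutrophil-like and 7 of 95 in stroma or fibroblast-like cells, 9 of 145 over all kept cells and 1 of 28 for the difference between classes. All but those of neutrophil-like cells and of the difference exceeded the 5% of the threshold.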

Other observations

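All values and tests in this part were chosen after the result was seen.

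Among the unnamed clusters, cluster 15 (164 cells) stood out by its genes. Fcgr4, an Fc receptor gene, stood at 3339 CPM against 189 CPM in the macrophage-like clusters 2 and 6, Cd72 at 1171 against 190.6 CPM, Acp5 at 873 against 278 CPM and Fcrl5 at 307 against 1.14 CPM. Cdkn2a, a cell cycle inhibitor gene whose separate products were not told apart, stood at 161 CPM in cluster 15 and 1.95 CPM in clusters 2 and 6. Cluster 15 held 0, 2 and 5 cells in the 3-month pools and 22, 2 and 133 in the 15-month pools, so most of it came from 1 pool, and its share did not pass the test (log2 ratio 4.03 ± 1.64, SE, edgeR adjusted p = 0.348). Over all kept cells Cdkn2a stood at 0, 0.50 and 1.30 CPM in the 3-month pools and at 10.24, 3.13 and 21.97 CPM in the 15-month pools (edgeR adjusted p = 0.163). The pools did not overlap, which held for 24.2% of genes tested over all kept cells where chance gives 10%, and the levels came from 0, 2 and 10 UMIs against 59, 69 and 182. The count of 0 UMIs in the first 3-month pool does not exclude low levels there.

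Cluster 1 (437 cells) carried Ccr2, a monocyte chemokine receptor gene, at 817 CPM against 191 CPM in clusters 2 and 6. Cluster 16 (34 cells) carried Saa3 at 10060.0 CPM, Prg4 at 5566 CPM, Alox15 at 2318 CPM, Timd4 at 307 CPM and Cd5l at 1149 CPM, each at 17.6 CPM or less in clusters 2 and 6. Cluster 17, one of the neutrophil-like clusters, carried Acod1 at 4192 CPM and Slc7a11 at 3248 CPM, with 9, 2 and 0 cells in the 3-month pools and 6, 107 and 8 in the 15-month pools, which overlapped in share (edgeR adjusted p = 0.468). Cluster 5, one of the classical monocyte-like clusters, carried Arg1 at 2738 CPM, Ccl2 at 6799 CPM, Ccl7 at 4190 CPM and Spp1 at 5377 CPM, and none of its 174 cells came from the third 3-month pool, of 920 cells. Cells with over 1% haemoglobin UMIs numbered 4, 4 and 18 in the 3-month pools and 0, 1 and 0 in the 15-month pools, and 20 of those at 3 months and the 1 at 15 months were cDC1-like.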
